A study of Ovis aries with 6 samples.

How the data were processed

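The series holds 6 sheep samples labelled hypothalamus, 3 from small-tailed Han sheep (HP) and 3 from Wadi sheep (LP), as given by the labels and the series' design text, and no batch, pairing or other covariate is stated. RNA was made into full-length cDNA, amplified by PCR and sequenced on an Oxford Nanopore instrument, per the labels' protocols. The submitters' processing notes name the aligner minimap2, version 2.17-r941. The quantification tool, genome build, gene annotation and filters are not given in the sources used here. The deposited estimated counts per gene were not scaled between samples, and between 24.0% and 29.8% of the values in a library were not whole numbers. The deposited TPM values, scaled by the authors to the same total in each sample, were at 0 in the same cells as the counts, and how they treat transcript length is not stated. Each table named its columns with another letter than the sample titles, so columns were matched to samples by number alone. No label explains the letter.

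Estimated counts were rounded to whole numbers before any count test, which moved a library total by at most 101 counts. Rounded totals in HP replicates 1, 2 and 3 were 2332067, 2732911 and 2642721, and in LP replicates 1, 2 and 3 2284589, 2419526 and 1981644. At this depth 3 counts, the limit that a count of 0 allows, stand for 1.10 to 1.51 CPM, the counts of a gene scaled to the library total. Amplified reads are not independent molecules, so intervals and floors here cover counting error only. Of 26067 features, 21457 had a gene name in the tables, 5317 of them LOC names, and 4610 were loci without a gene name. Names were compared with a RefSeq gene table of assembly ARS-UI_Ramb_v3.0, used for names only, which held 20348 of them (94.8%). Reads of near-identical gene copies could be split between them in counting, and members of such families are uncertain.

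Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 13078, libraries were scaled with TMM factors, and HP was compared with LP with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard prior, without the robust option, was used. Log2 fold changes are HP minus LP, and folds are given as the higher over the lower group. CPM levels of genes use the TMM-scaled totals, and summed CPM of gene lists use the library totals. A gene with no count in all libraries of a group was given a lower bound of its fold, against a floor of 3 counts in each of these libraries. A gene with 1 to 3 counts in a group was given the ratio of summed CPM with a 95% counting interval. Shares of the counts of single libraries have 95% Wilson intervals. With 3 sheep per breed, given by the labels as separate samples, p-values of this gene test measure the spread between these samples.

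Gene lists were fixed from general knowledge before the data were examined. They covered the GnRH network, energy balance, neurosecretory hormones, photoperiod and thyroid signalling, the circadian clock, BMP and activin signalling, steroid synthesis, GABA, glutamate and monoamine signalling, synaptic vesicles, myelin, immediate early genes, heat shock and protein folding, the interferon response, antigen presentation, the respiratory chain, ribosomal proteins, the mitochondrial genome, hypothalamic nuclei, telencephalon, striatum and thalamus. Cell type lists covered neurons, astrocytes, oligodendrocytes and their precursors, microglia and macrophages, endothelium, mural cells and fibroblasts, ependyma and tanycytes, choroid plexus, anterior pituitary, erythroid cells and leukocytes, with Y-linked genes as a check. Lists with at least 3 tested genes, and KEGG and GO terms of the deposited annotation with 10 to 300 tested genes, were tested with camera in limma 3.58.1. It ran on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the lists or over the terms of each source. Camera with an estimated correlation and fry, a test of whether the genes of a set move one way on balance, were run beside it. Some lists share members. Certain genes of these lists are not reported here by name.

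Genes were named by a rule written before the data were examined. It took the 10 genes with the largest change in each direction among named genes past the threshold whose HP and LP values did not overlap, LOC names left out. It added every member of the GnRH network and energy balance lists with an unadjusted p under 0.05, 16 peptide and receptor genes whatever their result, and up to 4 members of each other list with the smallest p. Another 6 lists were drawn up after the data had been examined. They were 11 cerebellar genes whose values had been seen, 25 further cerebellar genes and 15 pituitary regulators whose values had not been looked at, 7 pituitary hormones, 15 hypothalamic peptides, and the choroid plexus list without TTR and KL. Among these, 7 of the pituitary regulators and 2 of the 25 cerebellar genes also stood in a list fixed earlier. TTR and members of these lists outside the rule were therefore chosen after the data had been examined.

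The gene test was tested on simulated data drawn from the means and library sizes of these samples, in which 200 of 13078 genes were changed. It recovered 2% of genes changed 2-fold, 28% changed 4-fold, 90% changed 8-fold and 94% changed 16-fold, with 8 calls among 12878 unchanged genes. Far more genes, 6693, were called in the data, where the adjustment is therefore less strict. These shares hold for the simulated setting and do not give the recovery in the data. The simulation also held no shift of highly abundant transcripts between the groups beyond the changed genes. Alternatives were other size factors, library totals alone, no filter and a stricter filter of 10 counts, DESeq2 1.42.0, limma-voom with and without sample weights, edgeR with a robust prior, limma on log2 of the deposited TPM with pseudocounts of 1 and 0.1, other thresholds, other set tests, and leaving out each library in turn. Chosen after seeing the data were alternatives without genes above 1% of any library, without both libraries high in TTR, and without loci lacking a gene name. All 10 ways of splitting the 6 samples into groups of 3 were run.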

Results

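Gene expression was measured by Nanopore sequencing of full-length cDNA in 6 samples labelled hypothalamus, the brain region that controls the pituitary and, through gonadotropin-releasing hormone (GnRH), reproduction. The HP group held 3 small-tailed Han sheep, which the submitters class as highly reproductive, and the LP group 3 Wadi sheep, classed as less reproductive. Breed and reproductive class were the same split. The libraries held between 1981644 and 2732911 counts over 26067 features, of which 21457 carried a gene name. Between 18480 and 19415 features were detected in each library. Table columns were matched to samples by their number alone, because the letter in the column names differs from that in the sample titles and no label explains it. Every statement about HP or LP below, and the tissue given for the counts, rests on that match.

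The HP libraries resembled each other more than the LP libraries did. Across genes, which are not independent replicates, Pearson's r of log2 CPM, the counts scaled to library size, was 0.950 to 0.970 within HP, 0.801 to 0.901 within LP and 0.525 to 0.632 between the groups. The first principal component separated HP from LP and held 74.5% of the variance, and the second, with 14.2%, separated the LP libraries from each other. In a check for a library deposited more than once, the chi-square statistic per degree of freedom was at least 5.69 in every pair within a group, and each library was counted as 1 sample. LP replicate 3 stood apart from the other LP libraries in glial transcripts, and LP replicate 1 in connective tissue transcripts, as the values of those lists show.

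**Figure D1:**
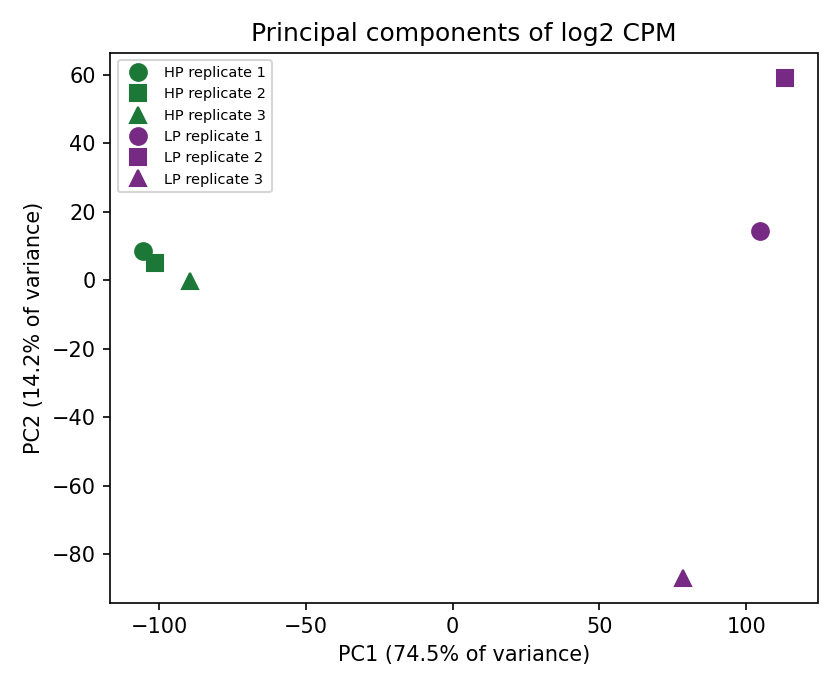
Principal components of log2 CPM of the tested genes, with PC1 (74.5% of the variance) on the horizontal axis and PC2 (14.2%) on the vertical axis, 1 point per library, HP in green and LP in purple. The 3 HP points lie close together between -105.6 and -89.3 on PC1, and the 3 LP points lie between 78.4 and 113.3 and spread from -86.8 to 59.1 on PC2.

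Anterior pituitary genes were higher in the LP libraries, and neuronal genes, together with cerebellar genes listed after the data had been examined, were higher in the HP libraries. PRL, which encodes the pituitary hormone prolactin, stood at 160064 ± 135911 CPM (SD, n = 3) in LP and 49.1 ± 39.2 CPM (SD, n = 3) in HP. NEUROD1, a transcription factor of cerebellar granule neurons and other neurons, stood at 707 ± 163 CPM (SD, n = 3) in HP and 1.49 ± 0.396 CPM (SD, n = 3) in LP. The hypothalamic peptide genes GNRH1, KISS1, OXT and AVP were at or near 0 counts in all 6 libraries, whereas TRH had counts in HP.

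The comparison addressed which genes differ between the tissue of a more and a less prolific breed. Of 13078 genes tested, 6693 (51.2%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3542 of them higher in HP and 3151 higher in LP. A fold of at least 2 was reached by 5896 of these genes and a fold of at least 16 by 771. The 3 HP values lay wholly above or below the 3 LP values in 8231 tested genes (62.9%), where chance gives 10%. Scaling and unit moved the split of directions. Library totals alone gave 63.0% of calls higher in HP instead of 52.9% and put the median of all tested genes at a log2 fold change of 0.27 instead of 0.02. The deposited TPM, tested with limma and so with another test as well as another unit, gave 36.2% and a median of -0.31 with a pseudocount of 1, and 35.1% and -0.40 with 0.1. Counts and shares of directions are therefore relative to the scaling and unit used.

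All 10 tested members of the anterior pituitary list were higher in LP (10 adjusted over the list alone), with a median log2 fold change, HP minus LP, of -9.98, or -8.89 with genes lacking any count in HP set at their bound (camera adjusted p = 8.01e-06, adjusted p = 0.431 with an estimated correlation). Without LP replicate 2 the anterior pituitary median was -8.39, and without HP replicates 1, 2 and 3 it was -9.05, -9.22 and -9.22. PRL took 12.1% (95% Wilson interval 12.1 to 12.1), 24.7% (95% Wilson interval 24.6 to 24.7) and 4.15% (95% Wilson interval 4.12 to 4.18) of all counts in LP replicates 1, 2 and 3. In HP replicates 1, 2 and 3 its share was 0.00999% (95% Wilson interval 0.00879 to 0.0114), 0.00296% (95% Wilson interval 0.00238 to 0.00368) and 0.00280% (95% Wilson interval 0.00223 to 0.00351). GH, which encodes growth hormone, was 4780.4-fold higher in LP and PRL 3264-fold, each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 7.37e-04 and adjusted p = 0.00104). POMC, the precursor of adrenocorticotropin, had 900, 615 and 222 counts in the LP libraries and 0, 2 and 2 in the HP libraries (adjusted p = 5.27e-04 by the same edgeR test with Benjamini-Hochberg adjustment). CGA, which encodes the alpha subunit shared by the gonadotropins and thyrotropin, had 8424, 34753 and 2928 counts in LP and 69, 37 and 45 in HP. LHB and FSHB, the beta subunits of luteinising and follicle-stimulating hormone, had 1179, 7065 and 350 and 286, 1910 and 69 counts in LP against 5, 1 and 1 and 1, 0 and 0 in HP. For FSHB this is a count ratio of 3149.5 with a 95% counting interval of 565 to 124454.

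LP replicate 2 held more counts of PRL, GH, CGA, LHB and FSHB than the other LP libraries, and without it the fold was 1789 for PRL, 2452 for GH, 149 for CGA and 414 for LHB, and 506 instead of a fitted 2226 for FSHB. Without HP replicate 1 it was 5726 for PRL and 3539 for LHB, and no HP count of FSHB was left. TSHB, the beta subunit of thyrotropin, had 17, 861 and 37 counts in LP and none in HP. It was at least 145-fold higher, or at least 12.6-fold without LP replicate 2. Its call by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0239) was lost without HP replicate 1, 2 or 3 (adjusted p = 0.0635, 0.0598 and 0.0559), and limma-voom gave adjusted p = 0.0564. Among the 10 genes with the largest change toward LP were also the developmental transcription factors SIX6 and NEUROD4, together with TENT5A, a poly(A) polymerase gene, and CLDN9, a tight junction gene. None of these 4 had a count in HP, and they were at least 156-fold (SIX6), 44.6-fold (NEUROD4), 88.8-fold (TENT5A) and 31.1-fold (CLDN9) higher in LP. Without LP replicate 2 the bounds were 89.7 (SIX6), 26.6 (NEUROD4), 28.4 (TENT5A) and 18.6 (CLDN9). A list of 15 pituitary transcription factors and receptors, drawn up after the data had been examined but without sight of its values, had 5 tested genes, of which 4 were higher in LP and SSTR2, a somatostatin receptor gene, was higher in HP.

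Of 15 hypothalamic peptide genes, gathered from the lists after the data had been examined, TRH alone had enough counts for a test. No count of GNRH1, KISS1 or NPVF was found in any library, which leaves a level of up to 1.10 to 1.51 CPM per library (3 counts). AVP had 1, 4 and 5 counts in the LP libraries and OXT had 4, 7 and 0. Both had none in HP. NPY had 4, 1 and 4 counts in LP and none in HP, and CRH had 1, 0 and 2 in HP and none in LP. SST had 1, 0 and 1 in HP and 0, 0 and 3 in LP, and GHRH 0, 1 and 1 in LP and none in HP. TAC3 had 1, 2 and 4 counts in HP and 1, 5 and 0 in LP, and PDYN 3, 7 and 9 and 1, 1 and 6. TRH, which encodes thyrotropin-releasing hormone, had 218, 399 and 317 counts in HP and none in LP, at least 73.6-fold higher in HP (adjusted p = 4.59e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). AGRP is not analysed here.

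In the GnRH network list, 5 of 9 tested genes were higher in HP and 2 higher in LP (8 past the threshold adjusted over the list alone), with camera adjusted p = 0.0471 and adjusted p = 0.431 with an estimated correlation. PENK, the proenkephalin gene, was 52.7-fold higher in HP, NELL2 5.82-fold and FGFR1 4.47-fold, each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 3.16e-04, adjusted p = 6.79e-04 and adjusted p = 0.00231). OPRM1, the mu opioid receptor gene, and PROKR2, the prokineticin receptor gene, were 38.3-fold and 27.3-fold higher in HP, or 135-fold without LP replicate 2 and 62.5-fold without LP replicate 1. GNRHR, the GnRH receptor of pituitary gonadotropes, was 29.9-fold higher in LP, or 9.44-fold without LP replicate 2, and missed the threshold with limma-voom (adjusted p = 0.0537). ESR1, which encodes oestrogen receptor alpha, had 72, 157 and 14 counts in LP and 10, 14 and 13 in HP and was 9.08-fold higher in LP, or 4.70-fold without LP replicate 2. The ESR1 call by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0134) was lost without HP replicate 1, 2 or 3 (adjusted p = 0.0630, 0.0566 and 0.0535) and with limma-voom (0.0632). ANOS1 missed the threshold of the same edgeR test with Benjamini-Hochberg adjustment (adjusted p = 0.0522). The list itself missed it without each library except LP replicate 2, with camera adjusted p from 0.0733 without LP replicate 1 to 0.416 without LP replicate 3, and 0.201, 0.223 and 0.238 without HP replicates 1, 2 and 3. It also missed it with library totals alone (0.0979), without a filter on low counts (0.784), with the stricter filter (0.0591) and without both libraries high in TTR (0.567). The median log2 fold change of the GnRH network was 2.48, 1.61 without HP replicate 2, 1.47 without HP replicate 3 and -0.21 without a filter on low counts.

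Among energy balance genes, 3 of 12 were higher in HP and 2 higher in LP (5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.882). BDNF, a neurotrophin gene, was 27.7-fold higher in HP (71.9-fold without LP replicate 2), NPY5R 6.68-fold (11.6-fold without LP replicate 1) and CPE, which encodes a prohormone-processing enzyme, 2.14-fold. NUCB2, the nesfatin precursor, was 7.35-fold higher in LP (4.34-fold without LP replicate 2), as was POMC, whereas INSR was not called (adjusted p = 0.0778 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The neurosecretory list split evenly, with 3 of 10 genes higher in each group (6 adjusted over the list alone, camera adjusted p = 0.938). CRHR1, a corticotropin-releasing hormone receptor gene, was 12.2-fold higher in HP, whereas the granin genes SCG2 and CHGA were 51.5-fold and 19.6-fold higher in LP, or 23.0-fold and 12.4-fold without LP replicate 2. The median and the mean of both lists had opposite signs, with a median of 0.05 and a mean of -0.50 for energy balance and -0.52 and 0.14 for neurosecretory hormones. The camera direction followed the mean in both.

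Neuronal transcripts were higher in HP. Of the neuron list, 15 of 18 tested genes were higher in HP and 0 in LP (15 adjusted over the list alone, camera adjusted p = 1.50e-05, adjusted p = 0.282 with an estimated correlation). RBFOX3, the NeuN gene, was 62.1-fold higher, STMN2, which encodes a tubulin-binding protein, 20.9-fold, and SCN2A, a sodium channel gene, 12.7-fold. Their adjusted p ran from 3.42e-04 to 4.82e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the synaptic vesicle list, 15 of 19 genes were higher in HP and 1 in LP (16 adjusted over the list alone, camera adjusted p = 9.19e-05, adjusted p = 0.431 with an estimated correlation). Among them were RIMS1 (25.4-fold), SV2B (20.2-fold), CPLX2 (18.3-fold) and SYN2 (15.6-fold). GABA signalling had 10 of 16 genes higher in HP and 1 in LP (11 adjusted over the list alone, camera adjusted p = 2.31e-04, adjusted p = 0.275 with an estimated correlation). GAD2, which encodes a GABA-synthesising enzyme, was 35.3-fold higher in HP, and the receptor gene GABBR2 was 8.72-fold higher. Glutamate signalling had 12 of 24 genes higher in HP and 2 in LP (15 adjusted over the list alone, camera adjusted p = 9.10e-04, adjusted p = 0.431 with an estimated correlation). GRIN2A was 28.5-fold and GRIA4 8.70-fold higher in HP. Its median of 1.80 became 2.60 without LP replicate 3.

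The genes with the largest change toward HP were SHISA8, TRH, NEUROD6, EN2, KCNS2, ARHGEF33, BARHL2, NEUROD1, PCP2 and UNC45B. SHISA8, NEUROD6, EN2, KCNS2, ARHGEF33 and BARHL2 had no count in LP and were at least 80.0-fold (SHISA8), 54.0-fold (NEUROD6), 43.0-fold (EN2), 29.8-fold (KCNS2), 18.0-fold (ARHGEF33) and 17.5-fold (BARHL2) higher in HP. EN2 is a patterning gene of the midbrain and hindbrain, and PCP2 is a Purkinje cell gene. PCP2 had 465, 498 and 428 counts in HP and 0, 0 and 2 in LP, a count ratio of 500.2 with a 95% counting interval of 138 to 4134, and no LP count was left without LP replicate 3. UNC45B, a myosin chaperone gene, had 705, 308 and 208 and 1, 0 and 1, a count ratio of 439 with a 95% counting interval of 121 to 3629, and its fitted fold of 399 was 240.5 without HP replicate 1. These genes moved together with others known from the cerebellum, in lists drawn up after the data had been examined. All 11 genes listed after their values had been seen were higher in HP, including the granule cell genes GABRA6 (164-fold), CBLN3 (90.7-fold) and FAT2 (52.3-fold). The fold of GABRA6 was 367 without LP replicate 2. Of 25 further cerebellar genes listed without sight of their values, 15 were tested. Of these, 13 were higher in HP and 0 in LP by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (13 by DESeq2 and 13 by limma-voom), with a median log2 fold change of 2.95. PCP4, expressed in Purkinje cells, was 5.42-fold higher in HP, whereas ITPR1 and GDF10 were not called by the same edgeR test with Benjamini-Hochberg adjustment (adjusted p = 0.934 and adjusted p = 0.288).

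Of other brain regions, telencephalon had 2 of 3 tested genes higher in HP (2 adjusted over the list alone, camera adjusted p = 0.0447, adjusted p = 0.431 with an estimated correlation). They were NEUROD6 and SLC17A7, a vesicular glutamate transporter gene also used by cerebellar granule cells, which had 856, 879 and 949 counts in HP and 2, 0 and 12 in LP (133-fold, or 590.0-fold without LP replicate 3). This list lost its call without each library except LP replicate 3 (camera adjusted p = 0.0572 without LP replicate 1, 0.324 without LP replicate 2, and 0.206, 0.223 and 0.238 without HP replicates 1, 2 and 3). The call was also lost with library totals alone (0.0632), without a filter on low counts (0.765) and without genes above 1% of any library (0.213). Its median of 7.06, or 5.76 with bounds, was 3.35 without LP replicate 2 and 9.20 without LP replicate 3. Without HP replicates 1, 2 and 3 it was 4.08, 4.05 and 3.79, and without a filter -1.33. Of 31 transcription factors in the list of hypothalamic nuclei that were among the features, only 8 had enough counts for a test. The tested part of this list went both ways, with 4 of 8 higher in HP and 3 in LP (7 adjusted over the list alone, camera adjusted p = 0.708), a median of 1.03 and a mean of -1.25. Camera gave the direction of its median. The thalamus list had 4 of 10 genes higher in HP and 0 in LP (4 adjusted over the list alone, camera adjusted p = 0.258), among them SYT9 (11.4-fold) and ADARB1 (5.32-fold). The striatum list had 2 of 7 higher in each group (4 adjusted over the list alone, camera adjusted p = 0.526), with PDE10A 2.71-fold higher in HP and DRD2 6.81-fold higher in LP.

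**Figure D2:**
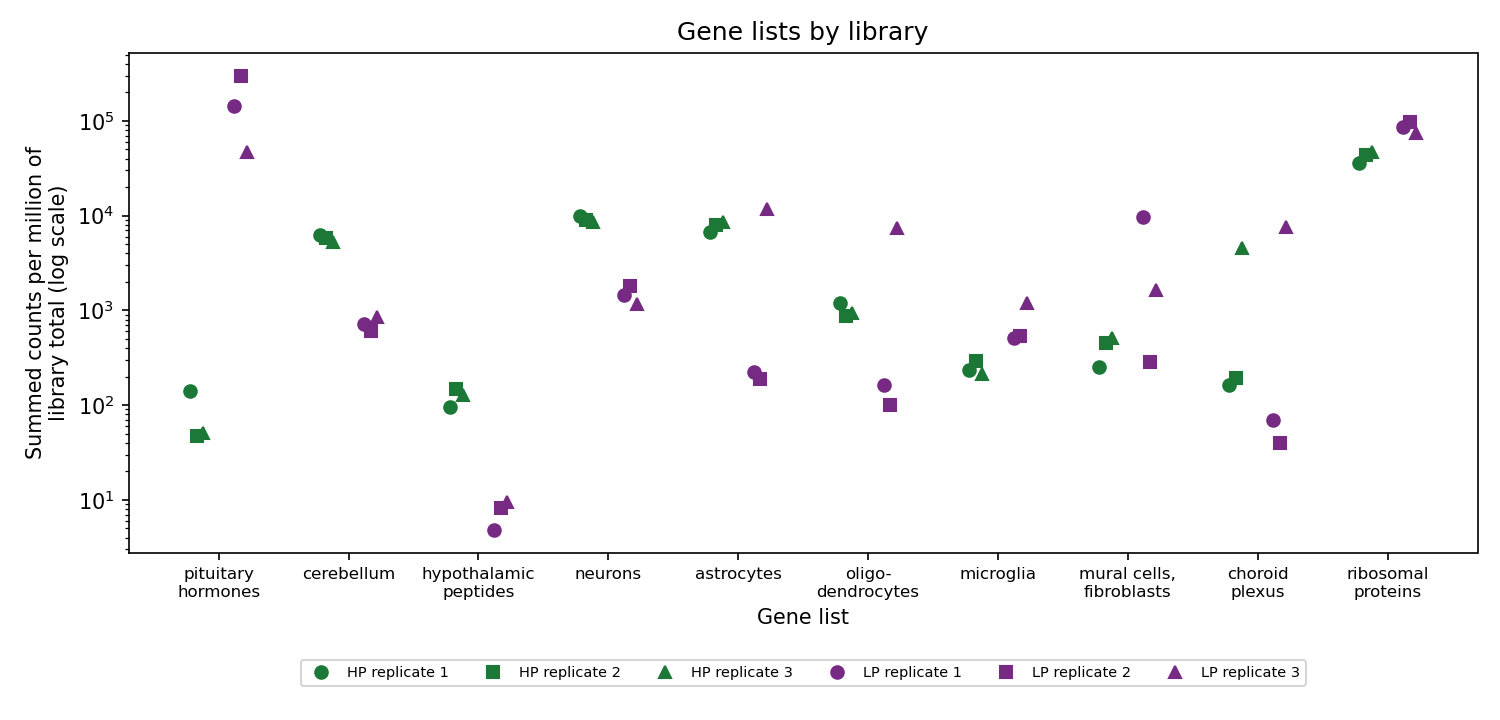
Summed CPM of the members of 10 gene lists in each library (vertical axis, log scale, 1 point per library, HP in green and LP in purple), where cerebellum is the list of 25 genes drawn up without sight of their values. Pituitary hormones lie between 47145.7 and 299657 CPM in LP and at no more than 139 CPM in HP, and cerebellar genes between 5298 and 6202 CPM in HP and at no more than 851 CPM in LP.

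Immune transcripts were higher in LP, together with the pituitary hormones. Of the interferon response list, 17 of 18 genes were higher in LP and 0 in HP (18 adjusted over the list alone, camera adjusted p = 2.48e-06, adjusted p = 0.431 with an estimated correlation). IRF9, a transcription factor of interferon signalling, was 9.62-fold higher and IFI35 8.74-fold. Their adjusted p ran from 8.14e-04 to 0.00178 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 11 tested antigen presentation genes were higher in LP (11 adjusted over the list alone, camera adjusted p = 3.69e-05, adjusted p = 0.275 with an estimated correlation). They included CD74, the MHC class II invariant chain gene (13.8-fold), PSMB8, an immunoproteasome gene (7.18-fold), and B2M, which encodes the light chain of MHC class I (5.41-fold). The list of microglia and macrophages had 10 of 13 genes higher in LP and 0 in HP (11 by DESeq2, 7 by limma-voom, 10 adjusted over the list alone, camera adjusted p = 0.00295, adjusted p = 0.431 with an estimated correlation). C1QB was 5.38-fold and CTSS 3.35-fold higher, and the list median of -1.95 became -1.29 without LP replicate 3. Only 2 leukocyte genes could be tested, CD3G of T cells and JCHAIN of plasma cells. Both were higher in LP (2 adjusted over the list alone), with 40, 56 and 20 CD3G counts in LP and 1, 2 and 13 in HP. Both calls were lost without HP replicate 2 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0529 for CD3G and 0.0620 for JCHAIN), and that of JCHAIN also without HP replicate 1 (0.0551). Without HP replicate 3 the fold of CD3G was 30.5 instead of 10.0, and that of JCHAIN 14.9 instead of 8.21.

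Members of the list of ribosomal proteins were also higher in LP, where 57 of 71 passed and 0 passed toward HP (59 adjusted over the list alone, camera adjusted p = 1.20e-14, adjusted p = 0.444 with an estimated correlation). They held 85649, 97815 and 75103 CPM of the LP libraries and 35636, 43592 and 47317 CPM of the HP libraries. The list median was -1.49, between -1.21 with library totals alone and -2.20 with the deposited TPM, below the median of all genes under each scaling. RPL15 (13.5-fold) and RPS2 (12.1-fold) were the most changed of the 4 named by the rule, followed by RPLP2 (4.31-fold) and RPL28 (4.05-fold). Copies of ribosomal protein genes can share reads, so single members are uncertain. Of the heat shock and protein folding list, 14 of 23 genes were higher in LP and 2 in HP (16 adjusted over the list alone, camera adjusted p = 0.00553, adjusted p = 0.444 with an estimated correlation). Among them were the endoplasmic reticulum folding genes DNAJB9 (4.03-fold), PDIA4 (3.30-fold) and PDIA6 (2.89-fold) and the mitochondrial chaperone gene HSPD1 (3.39-fold). Genes of the respiratory chain did not move as a set, with 7 of 51 higher in HP and 9 in LP (12 adjusted over the list alone, camera adjusted p = 0.415), except with the deposited TPM, where the respiratory chain passed toward LP (camera adjusted p = 0.00358). NDUFA13 was 2.73-fold higher in HP and ATP5PF 3.52-fold higher in LP, but with the deposited TPM the call of NDUFA13 was lost (limma adjusted p = 0.0651 with a pseudocount of 1 and 0.0623 with 0.1). Mitochondrially encoded genes held 20454, 10931 and 59909 CPM in LP replicates 1, 2 and 3 and 37033, 43770.5 and 37991 CPM in HP, so the LP libraries lay on both sides of HP. Of 12 tested mitochondrially encoded genes 2 were higher in HP and 0 in LP (0 adjusted over the list alone, camera adjusted p = 0.694). DESeq2 called 3 and limma-voom 2 of them, and 3 had an unadjusted p under 0.05 by edgeR.

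The list of immediate early genes had 9 of 21 higher in LP and 0 in HP (12 by DESeq2, 6 by limma-voom, 9 adjusted over the list alone, camera adjusted p = 0.0279, adjusted p = 0.738 with an estimated correlation). The list held 5819, 1137 and 650.5 CPM in the LP libraries and 428, 658 and 525 CPM in the HP libraries. Without LP replicate 1 its call was lost (camera adjusted p = 0.165) and its median went from -2.24 to -1.37, and without LP replicate 3 the median was -2.88. The call of immediate early genes was also lost in fry (0.219), with the deposited TPM (0.0849) and without unnamed loci (0.0655). EGR1, a transcription factor gene induced by neuronal activity and by GnRH in gonadotropes, had 903, 351 and 43 counts in LP and 4, 17 and 16 in HP (47.0-fold, or 23.2-fold without LP replicate 1). GADD45B was 3.66-fold higher in LP. The list of steroid synthesis and metabolism had 9 of 20 higher in LP and 0 in HP (10 by DESeq2, 6 by limma-voom, 9 adjusted over the list alone, camera adjusted p = 0.0471, adjusted p = 0.799 with an estimated correlation). IDI1, of isoprenoid synthesis, was 3.92-fold higher, TSPO, a mitochondrial translocator gene, 4.50-fold, and HSD11B1, which encodes a cortisol-regenerating enzyme, 14.6-fold, or 7.17-fold without LP replicate 2. The steroid call was lost without HP replicate 1, 2 or 3 (camera adjusted p = 0.105, 0.102 and 0.103) and without LP replicate 3 (0.258), where the median went from -1.40 to -0.79. It was lost as well without a filter (0.0956), with the stricter filter (0.0689), with the deposited TPM (0.125), in fry (0.236), without genes above 1% of any library (0.0550), without unnamed loci (0.157) and without both libraries high in TTR (0.251).

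Glial markers differed widely between the LP libraries. Oligodendrocyte genes held 164, 101 and 7361 CPM in the LP libraries and 1188, 869 and 938 CPM in the HP libraries. None (0 of 10) were called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone, camera adjusted p = 0.938). The myelin list gave 0 of 9 by each of the same counts (camera adjusted p = 0.882). Astrocyte genes held 225, 189 and 11745 CPM in LP and 6666, 7995 and 8538 CPM in HP, with 2 of 12 higher in HP and 0 in LP (3 by DESeq2, 5 by limma-voom, 0 adjusted over the list alone, camera adjusted p = 0.140). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the call of ALDOC was lost without each library except LP replicate 3 (adjusted p from 0.0714 to 0.0975) and with a robust prior (0.0580), and that of SLC4A4 without HP replicate 1 (0.0690), HP replicate 2 (0.0656) and LP replicate 1 (0.0571). Without LP replicate 3 the fold of ALDOC was 44.3 instead of 8.23 and that of SLC4A4 5.18 instead of 3.26. Precursors of oligodendrocytes had 1 of 7 genes higher in each group (2 adjusted over the list alone, camera adjusted p = 0.882), TNR in HP and VCAN in LP. In the myelin, oligodendrocyte and precursor lists the median was negative (-1.89, -1.54 and -1.78), as was the mean, whereas camera gave the direction of HP. Without LP replicate 3 the lists of myelin, oligodendrocytes and astrocytes passed toward HP (camera adjusted p = 0.00767, 0.00115 and 1.39e-05), with medians of 2.39, 2.39 and 3.71.

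The list of mural cells and fibroblasts held 9639, 284 and 1625 CPM in LP and 253, 458 and 506 CPM in HP, with 7 of 13 higher in LP and 0 in HP (8 by DESeq2, 4 by limma-voom, 9 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.679 with an estimated correlation). DCN, the decorin gene, was 15.2-fold higher in LP. IGF2 stood at 64.2 ± 38.2 CPM (SD, n = 3) in LP and 2.52 ± 0.532 CPM (SD, n = 3) in HP. This list lost its call without LP replicate 1 (camera adjusted p = 0.104, with the median at -1.41 instead of -3.36) and without LP replicate 3 (0.0685). It was also lost in fry (0.134), with the deposited TPM (0.0849) and without both libraries high in TTR (0.0925). Ependymal and tanycyte genes held 2550, 388 and 2032 CPM in LP and 166, 290 and 302 CPM in HP, with LP replicate 2 nearest to HP. They had 7 of 10 higher in LP and 0 in HP (8 by DESeq2, 5 by limma-voom, 7 adjusted over the list alone, camera adjusted p = 0.00646, adjusted p = 0.282 with an estimated correlation). Among them were RARRES2 (12.9-fold), DYNLRB2 (4.68-fold) and CRYM (4.17-fold). The endothelium list had 1 of 11 genes higher in HP and 3 in LP (4 adjusted over the list alone, camera adjusted p = 0.328). It passed toward LP without LP replicate 2 (camera adjusted p = 0.0192, median -2.37 instead of -1.26). Choroid plexus genes had 0 of 6 called by edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone, camera adjusted p = 0.942), as had the list without TTR and KL by each of these counts (0 of 4), set apart after the data had been examined. TTR, a leading transcript of that tissue chosen after its values were seen, had 246, 304 and 11947 counts in HP and 68, 11 and 14490 in LP. Erythroid genes had 2 of 4 higher in LP and 0 in HP (2 adjusted over the list alone, camera adjusted p = 0.203), with GYPC 6.16-fold higher. Y-linked genes are not analysed here.

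Circadian clock genes had 6 of 16 higher in HP and 2 in LP (8 adjusted over the list alone), without a call for the circadian clock (camera adjusted p = 0.188) unless unnamed loci were removed (camera adjusted p = 0.0455). CRY2 was 9.76-fold and NR1D2 5.91-fold higher in HP, both of them repressors in the clock, and PER3 was 2.88-fold higher. Photoperiod and thyroid signalling genes had 2 of 12 higher in HP and 5 in LP (7 adjusted over the list alone, camera adjusted p = 0.302). DIO2, which encodes the enzyme that activates thyroid hormone, was 10.9-fold higher in LP, or 6.78-fold without LP replicate 2, and CHD7, a chromatin remodeller gene, 5.21-fold higher in HP. Of the BMP and activin list, 2 of 24 genes were higher in HP and 6 in LP (8 adjusted over the list alone, camera adjusted p = 0.328). BMPR1B, the gene of the sheep fecundity locus FecB, had 12, 8 and 12 counts in HP and 2, 5 and 12 in LP and was not called (adjusted p = 0.746 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ID3, a target of BMP signalling, was 17.8-fold higher in LP (10.5-fold without LP replicate 1) and SMAD3 4.55-fold higher in HP. Monoamine signalling had 2 of 5 higher in LP and 0 in HP (2 adjusted over the list alone, camera adjusted p = 0.302), namely DRD2, the dopamine receptor gene through which dopamine lowers prolactin release, and MAOA (4.32-fold).

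**Figure D3:**
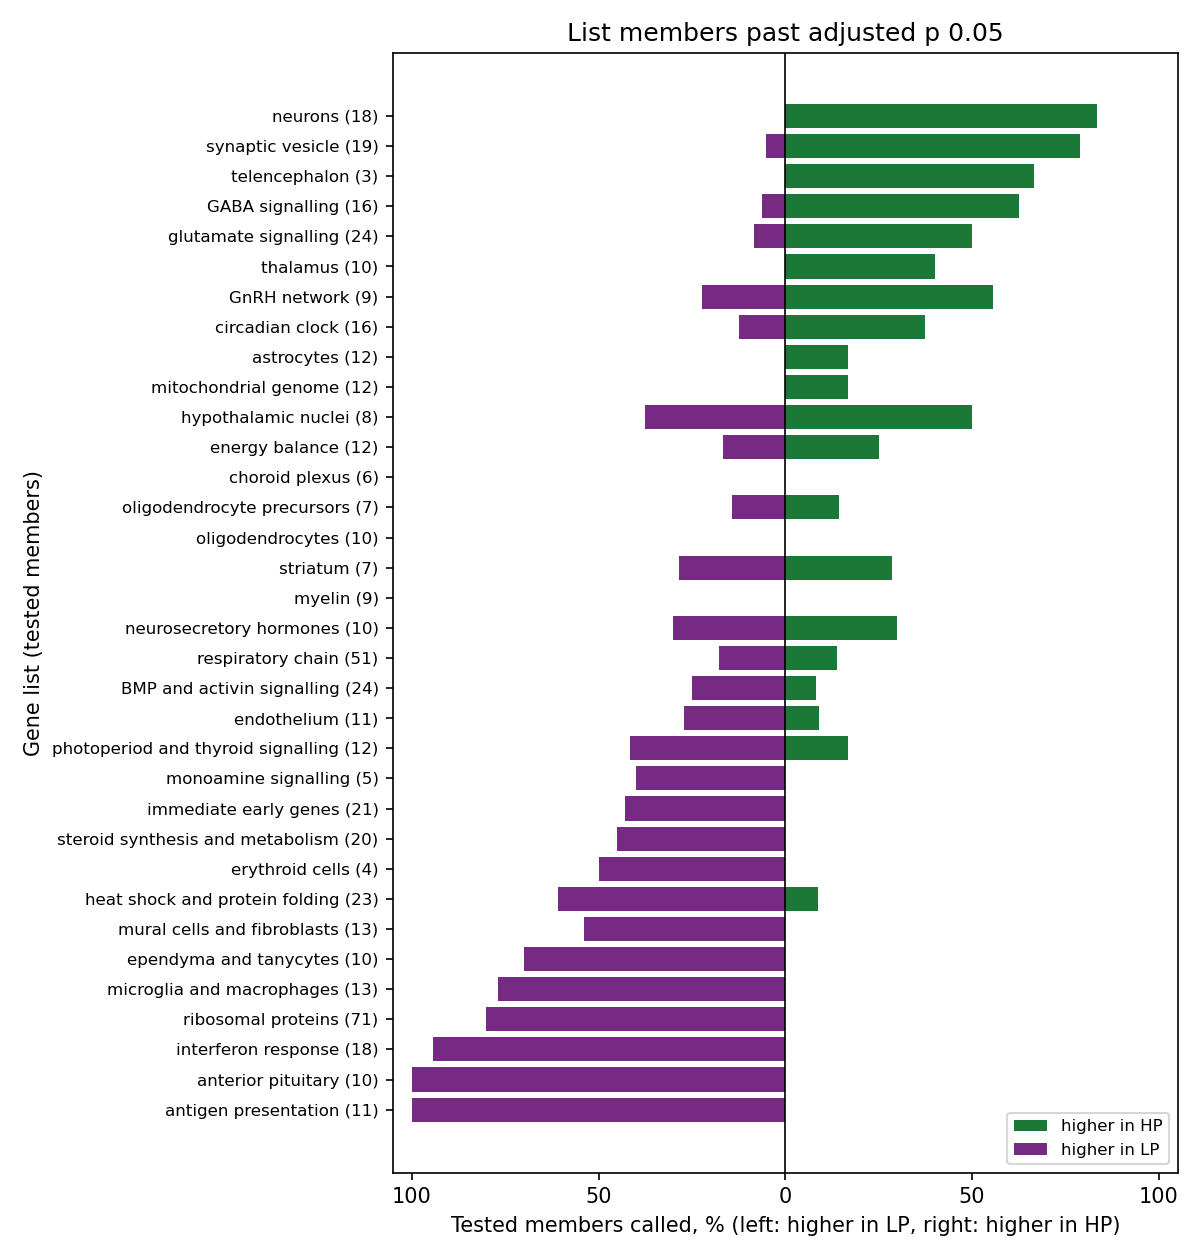
Share of the tested members of each gene list (horizontal axis, percent, starting from 0 in the middle) that passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, with genes higher in HP in green to the right and genes higher in LP in purple to the left, and the number tested in brackets. Neuron and synaptic lists extend to the right, with 15 of 18 neuron genes higher in HP, and antigen presentation and anterior pituitary lists reach the left end, with all 11 and all 10 tested members higher in LP.

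Of 730 GO terms 110 passed in camera, 25 toward HP and 85 toward LP, and of 315 KEGG pathways 59 passed, 7 toward HP and 52 toward LP. Among those toward HP were the KEGG pathway of Nicotine addiction (17 of 23 genes higher in HP and 0 in LP, camera adjusted p = 4.64e-06, adjusted p = 0.465 with an estimated correlation) and the GO term GABA-ergic synapse (11 of 14 genes higher in HP and 1 in LP, camera adjusted p = 0.00164, adjusted p = 0.534 with an estimated correlation). Toward LP stood Antigen processing and presentation (0 of 51 genes higher in HP and 35 in LP, camera adjusted p = 4.89e-07, adjusted p = 0.465 with an estimated correlation) and cytosolic large ribosomal subunit (0 of 63 genes higher in HP and 43 in LP, camera adjusted p = 8.04e-09, adjusted p = 0.550 with an estimated correlation). The term hormone activity had 7 of 12 genes higher in LP and 1 higher in HP (camera adjusted p = 0.0379, adjusted p = 0.534 with an estimated correlation). The pathway GnRH secretion, with 17 of 40 genes higher in HP and 5 in LP, did not pass (camera adjusted p = 0.135).

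In all, 16 of the 34 tested lists passed in camera with its preset correlation, 6 toward HP and 10 toward LP. None of the lists and none of the terms passed with an estimated correlation (smallest adjusted p of 0.275 for lists, 0.534 for GO and 0.465 for KEGG). There, 4 lists, 64 GO terms and 30 KEGG pathways had an unadjusted p under 0.05, and 19 lists, 442 GO terms and 156 KEGG pathways passed in fry. With 3 sheep per breed the p-values of single genes measure the spread among these animals. Camera with its preset correlation compares the genes of a set with other genes, so its p-values rest mainly on the spread across genes. Splits that mixed HP and LP libraries also passed 10 to 15 lists and 34 to 122 terms in camera, while calling 0 genes. Each of them keeps part of the difference between HP and LP and adds the rest to the spread within its groups. Their counts are therefore not those of groups without a difference.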

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

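The number of genes called by edgeR stayed within 1.5 times of 6693 under every alternative run, from 4794 without HP replicate 2 to 7932 at an adjusted p of 0.1, and from 4794 to 7913 over the libraries left out in turn. Among genes called both there and in the reported comparison the direction was opposite for 7 with the deposited TPM, at either pseudocount, and for none under the others. Of the settings chosen after seeing the data, removing genes above 1% of any library gave 6707 calls, leaving out both high-TTR libraries 7184, and removing unnamed loci, with fewer genes tested, 4854. With an estimated correlation, 0 lists and 0 terms passed in camera, where 4 lists, 64 GO terms and 30 KEGG pathways had an unadjusted p under 0.05, and the cause was not tested. For terms, fry, which does not compare a set with other genes, gave 598, and the removal of unnamed loci gave 106 instead of 169, for which the cause was not tested. Over the libraries left out in turn, the lists past the threshold numbered 12 to 17 and the terms 124 to 177. Results were counted once for each list or named gene under each alternative. Of the list results, 476 kept direction and side of the threshold, 15 gained a call and 53 lost it. Of the results of named genes, 3050 kept both, 49 gained a call, 82 lost it and 13 changed direction. The last came mostly from glial and choroid genes not called in the comparison. Their log2 fold changes over the libraries left out ran from -2.51 to 1.26 for ASPA, -1.73 to 2.33 for KCNJ13, -2.49 to 4.34 for MAG, -1.61 to 3.78 for SLC13A4, -1.65 to 0.92 for TF and -3.98 to 2.30 for UGT8. These changes were positive only without LP replicate 3, the library that held most of the LP counts of these genes. With both high-TTR libraries left out they were 1.22 (ASPA), 2.28 (KCNJ13), 3.97 (SLC13A4), 0.92 (TF) and 2.40 (UGT8). TGFBR3 went from -1.97 to 0.36 and 0.38 with the deposited TPM at pseudocounts of 1 and 0.1, and the cause was not tested. DESeq2 gave no adjusted p for 101 genes. No paired analysis was possible because the labels number the samples from 1 to 6 with no number shared between the groups. At this depth 11 of 15 hypothalamic peptides had 10 counts or fewer over all 6 libraries.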

Other observations

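Chosen only after the result was seen were the library-size tests, the test of hypothalamic peptides, the tests of choroid plexus tissue in each single library, the split counts of genes, and the lists of pituitary regulators and cerebellar genes as such. Loci without a gene name took 19.6% ± 0.438 (SD, n = 3) of counts in HP and 12.9% ± 2.59 (SD, n = 3) in LP, and 1708 of the 6693 called genes were such loci. The 10 most abundant genes took 11.1% ± 0.321 (SD, n = 3) in HP and 25.3% ± 10.1 (SD, n = 3) in LP. S100B, a glial calcium-binding protein gene chosen after its values were seen, had 7689, 12276 and 10870 counts in HP and 236, 241 and 18514 in LP.

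The 7 pituitary hormones took 16.3% ± 12.8 (SD, n = 3) of all counts in LP and 0.00790% ± 0.00523 (SD, n = 3) in HP, with means of 9.46% without LP replicate 2 and 0.00488% without HP replicate 1. LP totals were 0.867 times those of HP. Values had already been scaled to library totals, so library size could hardly give such folds and this comparison decides little. Without genes above 1% of any library the 7 pituitary genes left had a median log2 fold change of -9.38. The hormones took at most 30.0% of a library, so distorted scaling could hardly give such folds and this check decides little as well. Hypothalamic tissue in both groups with a breed difference is argued against only for the peptide genes chosen, of which 1 of 15, TRH, lay above the median tested gene in either group. All 15 stood in lists fixed earlier, but they were gathered after the data had been examined. PENK (90.1 CPM in HP) and POMC (284 CPM in LP), peptide genes of the same fixed lists, were left out. Both lay above that median, which was 18.0 CPM in HP and 18.4 CPM in LP. Pituitary tissue in the LP libraries is a candidate explanation, since 15 pituitary regulators that are not hormones, 7 of them in lists fixed earlier, had a median log2 ratio of HP to LP of -2.94, with 13 below 0. Of those below 0, NR5A1 had 1 count and AVPR1B 3 in LP, with none in HP, and SSTR5 had 5 in LP and 2 in HP. Whether breed or dissection lies behind it stays open, because breed is the same split as the groups, dissection is not stated as a covariate, and neither was tested. The hormone share also differed within LP, at 14.2%, 30.0% and 4.71% in replicates 1, 2 and 3. The match of columns to samples bears on which group holds these libraries, and on whether they are the samples labelled hypothalamus at all. It does not bear on the hormone counts in them.

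Cerebellar genes seen beforehand had 32372 counts in HP and 204 in LP. The trend on implied transcript length took up little of the change in the 26 tested cerebellar genes. Their median log2 fold change was 5.30 before and 4.89 after it was subtracted. These 26 include the 11 genes listed after their values had been seen, which raises both medians. The 15 others had a median of 2.95 before, and the length trend was not tested on them alone. HP totals were 1.15 times those of LP, and values had already been scaled to library totals, so library size could hardly give such folds. Cerebellar tissue in the HP libraries is a candidate explanation, since 25 genes whose values had not been looked at, 2 of them in lists fixed earlier, had a median log2 ratio of 3.17 (3.14 without BARHL2, also among the 10 genes with the largest change toward HP), with 24 above 0 and NRGN at -2.56. NRGN also stands in the telencephalon list fixed earlier, so its value says little about cerebellar tissue. Among those above 0, TLX3 and PTF1A had 1 count each in HP, CDH15 2 and EN1 4, with none in LP. ITPR1 was above 0 on library totals (0.21) but at -0.04 with TMM scaling. Some of the 25 genes are also expressed in other neurons, including hypothalamic ones. The neuron list was higher in HP as well (camera adjusted p = 1.50e-05, adjusted p = 0.282 with an estimated correlation). Whether breed or dissection lies behind such a difference in tissue stays open and was not tested. The match of columns to samples bears on which group holds these libraries, and on whether they are the samples labelled hypothalamus.

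TTR had 246, 304 and 11947 counts in HP and 68, 11 and 14490 in LP, and its share of the library total in HP replicate 3 and LP replicate 3 was 41.7 and 426 times the mean share in the others of their group. The larger ratio of library totals was 1.04, and shares of the total already allow for library size. Over 9 other choroid plexus genes the median excess of these libraries on the log2 scale, averaged over both groups, was 1.10. This lay past the bound set beforehand, but through LP replicate 3 (1.64) and not HP replicate 3 (-0.062). The average therefore cannot decide for both libraries together. Choroid plexus tissue may lie behind the TTR counts of LP replicate 3, where FOLR1, KCNJ13 and SLC13A4 were also higher. Of the 9 genes CAB39L alone was lower there, with 21 counts against 40 and 51 in LP replicates 1 and 2. Astrocyte genes also held 11745 CPM in LP replicate 3 against 225 and 189 CPM in LP replicates 1 and 2. In HP replicates 1 and 2, where TTR was low, KCNJ13 had 15 and 19 counts and SLC13A4 24 and 89. LP replicates 1 and 2 had 3 and 2 counts of each. The excess in LP replicate 3 therefore does not by itself single out choroid plexus tissue. In HP replicate 3 choroid plexus tissue stays open as an explanation. There KCNJ13 had 20 counts (15 and 19 in HP replicates 1 and 2) and FOLR1, AQP1 and OTX2 had 1, 0 and 0. By contrast, CLIC6 had 7 (4 and 0) and KL, which the median leaves out, 16 (0 and 3). No biological explanation other than tissue was tested.

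The 10 splits of the 6 samples into groups of 3 are too few for a share under 0.05. The real split called 6693 genes and the highest of the others 0 by edgeR, where the other splits had 27 to 252 genes at an unadjusted p under 0.05, so 1 split gave as many genes. For lists past the threshold 1 split gave as many, with 16 against 15 in the highest of the others, and for terms 1 split, with 169 against 122. The lowest counts among the other splits were still 10 lists and 34 terms. All the other splits mix HP and LP libraries, which leaves part of their difference between the groups and raises the spread within them. Neither their gene calls nor their lists and terms therefore show what groups without a difference would give.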
